A study of Mus musculus with 4 samples.

How the data were processed

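Gene expression was measured in GC-1 cells, a mouse spermatogonial cell line, on 4 one-colour Agilent mouse 8x60k arrays. Per the labels' protocols, cells were transfected with a plasmid carrying murine Hdac6 under a CMV promoter with a myc/DDK tag, or with the empty vector, and harvested after 48 h. Total RNA was copied from an oligo-dT primer and labelled with Cy3 by in vitro transcription. Each group has 2 arrays, numbered 1 and 2 in the labels. The labels do not say whether these came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

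Per the file headers, the scanner files hold spot intensity values extracted with Feature Extraction 11.5.1.1 under protocol GE1_1105_Oct12, and the processed intensity is background-subtracted and detrended but not normalized between arrays. The submitters' processing notes name Agilent Feature Extraction. Probe positions are those of the files, build mm9 (NCBI37), and 1-based. All 4 arrays were on 1 slide and scanned on 1 day, so neither can act as a batch. The authors also deposited a value table of log2 values with 37060 rows, 1 per gene name. How it was made is not given in the sources used here. Its scale was worked out by setting each column against the same array's scanner values. For the 25183 rows whose gene name has 1 probe and matches the array, the column differed from log2 processed intensity by a constant per array in over 99.9% of rows (99.96% on the array with the lowest share, tolerance 0.01), which fixes scale, direction and centring for those rows. The medians of its columns were -3.78 and -3.67 for the empty vector arrays and -3.71 and -3.68 for the Hdac6 vector arrays. The value table served as an alternative only.

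Each array holds 62976 spots, 59305 of them not controls. Log2 processed intensities were averaged over the 10 spots of each of 300 repeated probes, which left 56605 probes, and each array's 75th percentile was subtracted. Of the probes, 43838 were matched to a gene of the GRCm38.p6 RefSeq table by accession, symbol or synonym, 2155 took an updated symbol, and 12767 kept the name in the files. The reference was used for names alone. A probe was tested if it was well above background, by the scanner software's flag, on both arrays of at least 1 group. This left 35214 probes for 23461 genes or other names. Where 1 probe stands for a gene, it is the brightest tested probe by mean over the 4 arrays.

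The comparison of the Hdac6 vector with the empty vector was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of the spread with signal). Tests were two-sided with Benjamini-Hochberg adjustment over all tested probes, and changed means an adjusted p under 0.05. The fit has 2 residual degrees of freedom per probe, and the shared spread added 6.98. Intervals are 95% intervals of that fit. Log2 fold changes are Hdac6 vector minus empty vector. Where a probe was not well above background on either array of a group, the fold is given as a bound, the bright group's mean against the dim group's mean with the dim arrays raised to the lowest signal among probes well above background. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, for 32 lists with at least 5 tested genes, with Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry were run beside it. Counts "adjusted over the list alone" use the members' p-values only.

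The gene lists, the rule for named genes, the designs and the alternatives were fixed before the data were examined. Named are Hdac6, Pfn2 and all other histone deacetylase and profilin genes, then the 10 largest rises and falls among changed genes whose groups do not overlap and which have a gene symbol, then up to 4 changed members of each list that shifted or holds a changed gene. Where fewer than 5 genes pass, the 10 with the smallest unadjusted p stand in as values only. This was the case here, since 2 genes passed. Any gene outside the rule is said to have been chosen after its values were seen.

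The functions were tested on simulated data with the means and spreads of the 35214 tested probes and 200 changed probes. For the comparison of 2 against 2 arrays, 50 probes were simulated at each size. Recovered were 8 at 2-fold (16%), 46 at 4-fold (92%), 50 at 8-fold (100%) and 50 at 16-fold (100%). Beside these, 23 unchanged probes were called, a larger share of the calls than the threshold of 0.05. With no simulated change, 1 probe was called. In the list step on 23461 genes, the 1 simulated list was called and 0 others were. The simulated genes varied independently, without structure shared between arrays. In the data the lists that camera called had estimated correlations between genes of 0.15 to 0.63. The simulation thus cannot show how often lists or probes are called falsely in these data.

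Alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, scaling to 8 spike-in controls, no filter on dim probes, a filter on all 4 arrays, outlier spots left out, no trend in the spread, a robust spread, the replicate number as a block, the authors' value table, the mean of a gene's probes, an estimated correlation, the other Pfn2 probe, and each array left out in turn. A crossed replicate block and the value table's rows for genes with 1 probe were added after seeing the data. The crossed block puts empty vector 2 with Hdac6 vector 1, the closest pair of arrays, and empty vector 1 with Hdac6 vector 2. It takes the likeness of that pair out of the spread, so a pass with it is no separate support. Hdac6 has 1 probe on the array, so no other Hdac6 probe could be tried. Control spots were left out of all tests. No spot was saturated (0 on every array).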

Results

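The series measured what overexpression of Hdac6, a cytoplasmic deacetylase of tubulin and other proteins, does to the transcriptome of GC-1 cells, a mouse spermatogonial line. Cells that received the Hdac6 vector (2 arrays) were set against cells that received the empty vector (2 arrays), 48 h after transfection. On the empty vector arrays 66.4% and 65.1% of the spots were well above background, and on the Hdac6 vector arrays 64.3% and 61.0%. The 75th percentile of the processed signal was 1055 and 1081 on the former and 1279 and 717.5 on the latter. Empty vector 2 and Hdac6 vector 1 were the closest pair of arrays, 0.601% of 32601 probes differing by at least 2-fold between them, against 3.83% to 6.85% for the other pairs. The number of arrays limits the precision of every value.

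Hdac6 itself was measured first. The array's 1 Hdac6 probe gave 3.31 and 2.83 with the empty vector and 2.62 and 3.24 with the Hdac6 vector, as log2 signal relative to the array's 75th percentile. The difference was 0.908-fold (95% interval 0.578 to 1.43, n = 2 per group, limma adjusted p = 1.00), within the spread between replicates, and its sign turned without empty vector 1 (log2 0.10) or without Hdac6 vector 1 (log2 0.17). The probe lies on the X chromosome at 7507249 to 7507308 (mm9, minus strand). It holds an AATAAA polyadenylation signal at base 34 of its 60 bases, so it reads the 3′ end of the gene's own transcript. Whether the vector's insert holds that end is not given in the sources used here, so the probe need not read the vector's transcript.

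Pfn2 encodes profilin 2, an actin monomer binding protein, and the study's title names it as higher after Hdac6 overexpression. Whether the title rests on these arrays or on another measure could not be told, so it is not taken as independent evidence. Its brighter probe (chromosome 3, 57645886 to 57645945, mm9, minus strand) was well above background on all 4 arrays, at 4.40 and 3.47 with the empty vector and 3.45 and 3.87 with the Hdac6 vector. Pfn2 thus stood at 0.828-fold (95% interval 0.494 to 1.39, limma adjusted p = 1.00), opposite in sign to the title and not past the test, and its sign turned without empty vector 1 (log2 0.19). The dimmer Pfn2 probe (57649392 to 57649451) was not well above background on either Hdac6 vector array. By group means its signal there was lower by a bound of 1.21-fold (limma adjusted p = 1.00). The 95% interval of its log2 fold change, -1.62 to 0.26, allowed a rise as well. In the authors' value table, which has 1 row for both probes, the Pfn2 row read -0.40 and -0.43 with the empty vector and 3.72 and 3.98 with the Hdac6 vector, a log2 difference of 4.26 (limma adjusted p = 0.0115). On that table's scale the brighter probe was at 4.67, 3.73, 3.72 and 3.98 on the same arrays.

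**Figure D1:**
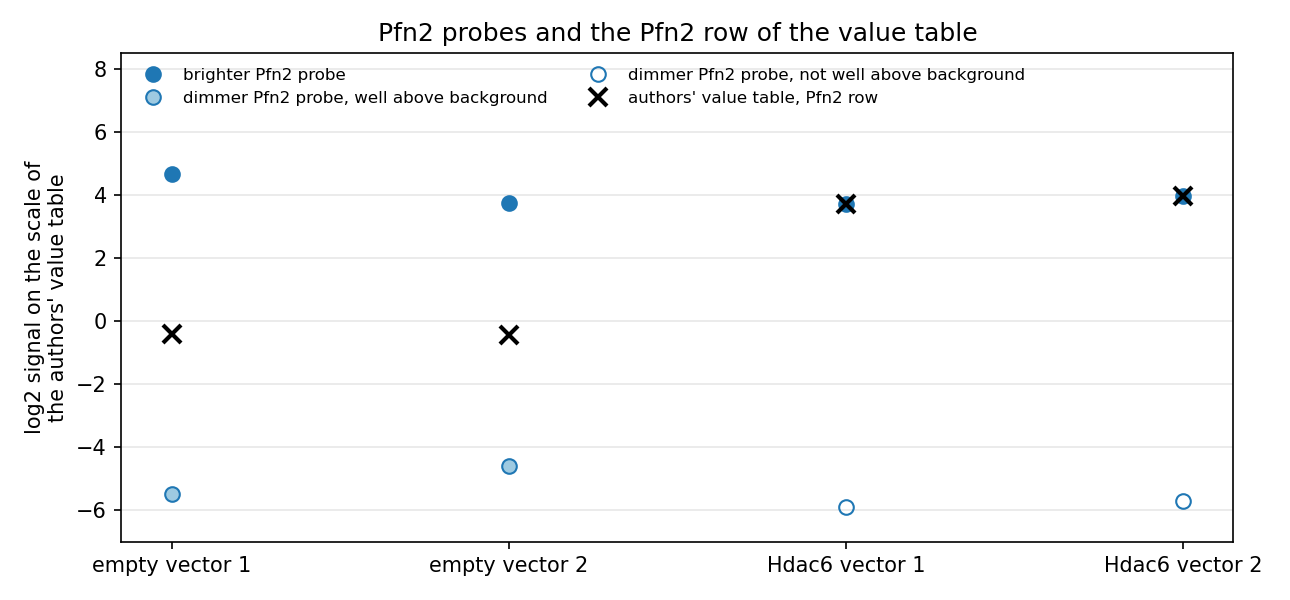
Log2 signal of both Pfn2 probes on each array (circles, on the scale of the authors' value table) and the Pfn2 row of that table (crosses); open circles were not well above background. The table's row lies between the probes on the empty vector arrays (-0.40 and -0.43) and on the brighter probe on the Hdac6 vector arrays (3.72 and 3.98).

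Pfn1 and the other histone deacetylases did not change. The brighter Pfn1 probe was at 1.06-fold (95% interval 0.713 to 1.57). Among the 10 other tested Hdac genes, the extremes were Hdac4 at 0.711-fold (0.441 to 1.15) and Hdac9 at 1.13-fold (0.661 to 1.95). Pfn3 and Pfn4 were not well above background on both arrays of either group and were not tested. Directions are not given for this family, since the sign of Hdac1, Hdac2, Hdac5, Hdac7 or Pfn1 turned under at least 1 scaling or background setting.

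Saa3 and Saa1, which encode serum amyloid A proteins of the acute-phase response, rose with the Hdac6 vector. Saa3 went from 3.79 and 4.02 to 6.25 and 6.63, a rise of 5.78-fold (95% interval 3.90 to 8.58, n = 2 per group, limma adjusted p = 0.0362). Saa1 went from 0.74 and 1.01 to 3.13 and 3.32, a rise of 5.10-fold (95% interval 3.51 to 7.41, limma adjusted p = 0.0362). Each has its probe on chromosome 7 (mm9, minus strand), Saa3 at 53967559 to 53967618 and Saa1 at 53996070 to 53996129. Both calls were lost without Hdac6 vector 1 (adjusted p = 0.355 for Saa3 and 0.672 for Saa1), without Hdac6 vector 2 (0.929 and 1.00) and with median scaling (0.0749 and 0.0982) or no trend in the spread (0.237 and 0.240), and that of Saa1 also with quantile normalization (0.0898), spike-in scaling (0.549) and the authors' value table (0.0806). Among the value table's genes with 1 probe neither passed (0.115 and 0.161), while the log2 fold changes with an array left out stayed between 2.34 and 2.72 for Saa3 and between 2.22 and 2.48 for Saa1.

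The other changed probes both carry the name Rsrc2, an arginine/serine-rich coiled-coil gene, and were chosen after their values were seen. One lies on chromosome 5 at 124192133 to 124192192 and the other at 124192190 to 124192249 (mm9, minus strand), so they overlap at their ends. They rose 13.7-fold (95% interval 8.54 to 22.0) and 16.7-fold (95% interval 9.68 to 28.7), each with a limma adjusted p of 0.0169, and the second was well above background on 1 of the 2 empty vector arrays. The brightest Rsrc2 probe, nearer the transcript's 3′ end at 124179182 to 124179241, was at 0.938-fold (95% interval of the log2 fold change -0.67 to 0.48, limma adjusted p = 1.00), and the other 2 tested Rsrc2 probes were at 1.04-fold and 1.09-fold. What rose was thus the signal of a stretch at the 5′ side of Rsrc2, measured by 2 neighbouring probes. Neither passed without Hdac6 vector 1 (adjusted p = 0.355 and 0.372), without Hdac6 vector 2 (0.929 for each) or with median scaling (0.0744 for each), nor the second with quantile normalization (0.0556), while their log2 fold changes with an array left out stayed between 3.64 and 3.91 and between 3.82 and 4.30. With normexp background correction, which adds an offset, their log2 fold changes were 2.43 and 1.94 in place of 3.78 and 4.06, and both passed.

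**Figure D2:**
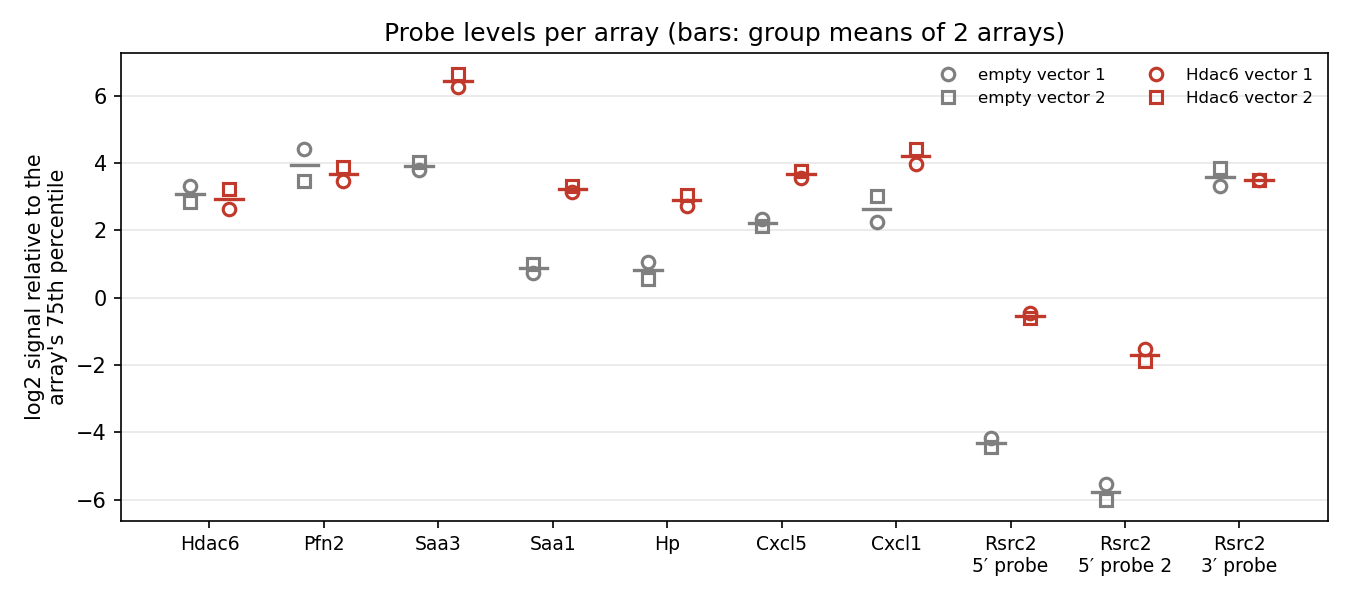
Log2 signal relative to the array's 75th percentile for single probes on each array (circles, replicate 1; squares, replicate 2; grey, empty vector; red, Hdac6 vector), with bars at the group means. Saa3, Saa1 and the 5′ probes of Rsrc2 passed the test, and the Hdac6, Pfn2 and 3′ Rsrc2 probes overlap or nearly overlap between groups.

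In all, 4 of 35214 tested probes changed (limma, adjusted p under 0.05), 4 up and 0 down, and all 4 by at least 2-fold. An unadjusted limma p under 0.05 was reached by 648. That is less than the share of 0.05 of the tested probes that no change at all would give, so this count is no sign of further changes. No probe passed (0) without Hdac6 vector 2 or with median scaling, where 651 and 727 had an unadjusted p under 0.05, while 310 passed without empty vector 2 and 20 without empty vector 1. The 2 probes that passed without Hdac6 vector 1 share 0 with the 4. Scaling to the spike-in controls gave 5 up and 1 down, and normexp background correction 21 up and 11 down.

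Among the genes with the next smallest p, given as values only, haptoglobin (Hp), another acute-phase protein, was at 4.24-fold (95% interval 2.79 to 6.43, adjusted p = 0.177). The neutrophil-attracting chemokine genes Cxcl5 and Cxcl1 were at 2.71-fold (1.88 to 3.90, adjusted p = 0.814) and 2.97-fold (1.83 to 4.81, adjusted p = 1.00). Values on the lower side were those of Grhl2, an epithelial transcription factor gene, at 0.313-fold (0.185 to 0.530, adjusted p = 1.00), and of Pramel31, a gene of the PRAME-like family, at 0.272-fold (0.154 to 0.482, adjusted p = 1.00), which was well above background on 1 of the 2 Hdac6 vector arrays. Dnah2, an axonemal dynein gene, and Zscan4f, a zinc finger gene of early embryos, were not well above background on either Hdac6 vector array. Their signal was at least 1.74-fold lower there (adjusted p = 0.177) and at least 2.06-fold lower there (adjusted p = 1.00). S100b, which encodes a calcium-binding protein, was likewise dim on both Hdac6 vector arrays and has no fold. Fits with an array left out hold a lone array in 1 group, without a spread of its own. Passes in them are therefore not given for these genes. Hp (limma adjusted p = 4.25e-08), Cxcl5 (0.000746) and Cxcl1 (7.97e-05) passed with normexp, and Hp with no filter on dim probes (0.000936). With the replicate block Hp (0.00207), Dnah2 (0.000574) and Zscan4f (0.0255) passed. With the crossed block Hp (9.15e-06), Dnah2 (0.0109), Cxcl5 (0.00155) and Cxcl1 (0.00940) passed. The crossed block follows the closest pair of arrays, so lower p-values were built in. With normexp the log2 fold changes were -0.46 for Pramel31 and -0.87 for Grhl2, in place of -1.88 and -1.67.

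NF-kB and inflammatory cytokine genes rose as a list, with 22 of 28 tested members higher and a median log2 fold change of 0.10 (camera adjusted p = 3.86e-05; adjusted p = 0.961 with an estimated correlation). Of its members 1 changed over all probes, Saa3, and 5 changed adjusted over the list alone. The other 4 were the chemokine genes Cxcl1, Cxcl5 and Ccl7 (2.24-fold) and Lcn2 (2.34-fold), which encodes an iron-siderophore binding protein of the acute phase. Over all probes Ccl7 passed with normexp and the crossed block. The chemokine gene Ccl2, picked after its values were seen, was at 1.66-fold (log2 0.73, SE 0.34) and did not pass. Without empty vector 1 the list's median was -0.14 and its camera adjusted p 0.638, and without Hdac6 vector 1 they were 0.27 and 0.0964. The median of the interferon and nucleic acid response genes was -0.04 (21 of 55 higher, camera adjusted p = 0.593), and that of the macrophage and leukocyte markers was 0.00 (7 of 14 higher, camera adjusted p = 0.987).

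Mitosis genes fell as a list, 36 of 40 being lower, with a median log2 fold change of -0.20 (camera adjusted p = 9.30e-05; adjusted p = 0.961 with an estimated correlation). All members of this list and of the immediate early and hypoxia lists named here were picked after their values were seen, and none passed. The kinase genes Bub1 and Aurka were at 0.736-fold and 0.774-fold, and the separase gene Espl1 at 0.723-fold. The DNA replication and S phase genes did not shift (24 of 41 higher, median 0.05, camera adjusted p = 0.593). Immediate early genes fell as a list, 23 of 29 being lower (median -0.21), among them the phosphatase genes Dusp4 (0.601-fold) and Dusp5 (0.712-fold) and the AP-1 gene Fosl1 (0.628-fold). Hypoxia and glycolysis genes fell as a list, 27 of 35 being lower (median -0.17), among them Ero1a (0.550-fold), the angiogenic factor gene Vegfa (0.681-fold) and the glycolytic gene Pfkp (0.758-fold). Both had a camera adjusted p of 0.00130 and an adjusted p = 0.961 with an estimated correlation. The mitosis call was lost without empty vector 1 (median -0.04, camera adjusted p = 0.849) and without Hdac6 vector 2 (-0.22, 0.338). The immediate early call was lost without empty vector 2 (-0.14, 0.176) and without Hdac6 vector 1 (-0.04, 0.159), and the hypoxia call without empty vector 1 (-0.03, 0.858) and without Hdac6 vector 1 (-0.05, 0.753).

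Mitochondrial respiratory chain genes rose as a list, 40 of 43 being higher (median log2 0.15, camera adjusted p = 0.00130), with Cox6b1 at 1.34-fold, Cox7c at 1.30-fold and Sdhc at 1.30-fold, picked after their values were seen. Cytosolic ribosomal protein genes rose as a list, 59 of 61 being higher (median 0.14, camera adjusted p = 0.00132), with Rps29 at 1.25-fold and Rpl34 at 1.24-fold, picked in the same way. Each had an adjusted p = 0.961 with an estimated correlation, and neither call held without empty vector 2 (medians 0.12 and 0.10, camera adjusted p = 0.253 and 0.504) or without Hdac6 vector 2 (medians 0.01 and -0.09, camera adjusted p = 0.522 and 0.463), nor with no filter on dim probes (0.120 and 0.190). The ribosomal call was also lost with the replicate block (0.0554) and among the value table's genes with 1 probe (0.0705). No member of these 2 lists, nor of the mitosis, immediate early or hypoxia lists, changed, over all probes or adjusted over the list alone (0 in each). Camera called 6 lists at the preset correlation and 0 with an estimated correlation, and fry called 0 lists (adjusted p = 0.969 for each). Other splits of the same arrays also gave list calls at the preset correlation, 4 for replicate 2 against replicate 1 and 7 for empty vector 2 and Hdac6 vector 1 against the rest. By replicate number the mitosis genes had a median of -0.17 (camera adjusted p = 1.09e-08), the NF-kB genes 0.25 (0.00291) and the ribosomal protein genes 0.19 (0.0126). In the other split the NF-kB genes had a median of 0.19 (0.00282), the hypoxia genes -0.34 (0.00117) and the ribosomal protein genes -0.31 (0.000569), so calls of these 4 lists were not particular to the vector.

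**Figure D3:**
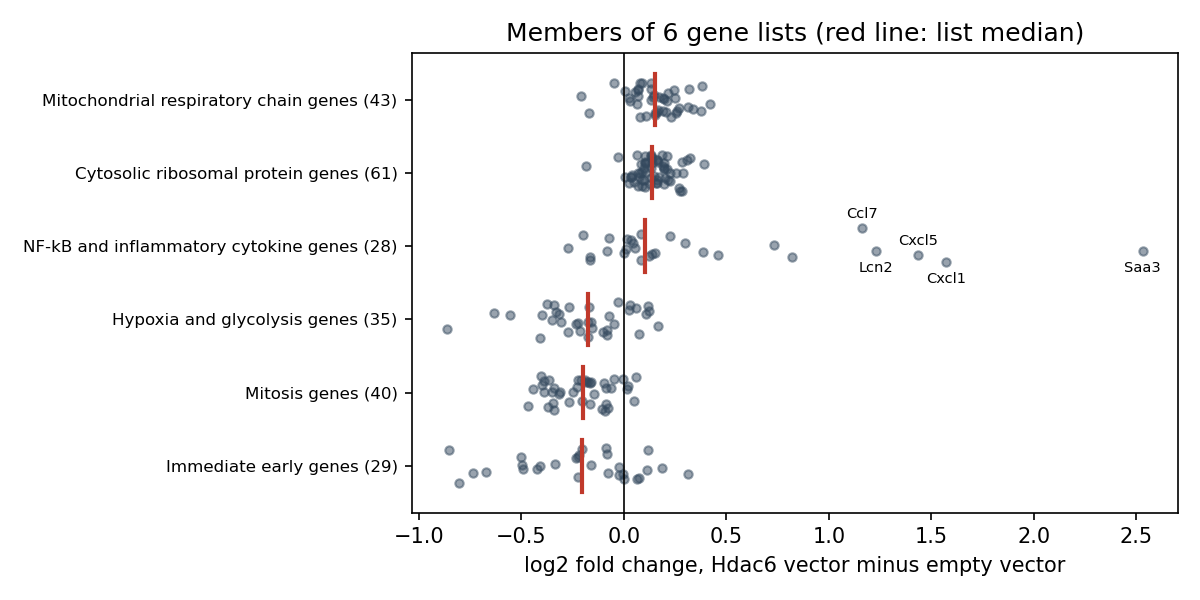
Log2 fold change (Hdac6 vector minus empty vector) of each tested member of the 6 lists that camera called at the preset correlation, with the number of members in brackets and a red line at each list's median. The medians lie between -0.21 and 0.15, while Saa3 stands at 2.53, and 0 lists were called with an estimated correlation.

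The lists for the cytoskeleton and for migration did not shift, and none of their members changed in the main fit. A probe of the actin nucleation gene Spire1, picked after its values were seen, passed as higher with the replicate block. Camera adjusted p was 0.790 for profilins and other actin monomer binding genes, 0.764 for actin nucleation, 0.617 for actin filaments and crosslinkers, 0.881 for integrins and focal adhesion, 0.562 for tubulins and microtubule regulators, 0.562 for cell junctions and 0.281 for migration and matrix genes. In the migration list the chemokine gene Cxcl12, picked after its values were seen, was at 1.33-fold (adjusted p = 1.00). The histone deacetylase and sirtuin list stood at 0.818.

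Stress and metabolism lists did not shift either. Camera adjusted p was 0.293 for heat shock and aggresome genes, 0.908 for the unfolded protein response, 0.172 for p53 targets, 0.593 for NRF2 targets, 0.790 for cholesterol synthesis, 0.790 for cell death regulators, 0.359 for autophagy and lysosome genes and 0.593 for histone genes. Of the testis lists, spermatogonia markers had a median of -0.16 (camera adjusted p = 0.264), with the growth-factor-responsive gene Etv5, picked after its values were seen, at 0.598-fold (adjusted p = 1.00). Meiotic germ cell markers had a median of -0.31 (camera adjusted p = 0.271), spermatid markers -0.01 (0.790), Sertoli cell markers -0.15 (0.312), Leydig cell markers -0.02 (0.790) and peritubular myoid markers 0.04 (0.593). Median, mean and camera's direction differed in sign for the profilin, actin nucleation, deacetylase, unfolded protein and macrophage lists, whose medians lay between -0.09 and 0.06.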

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

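The test of Pfn2's interval was chosen after its values were seen, and the averaging test after the values of Pfn2 and a few other genes had raised the idea but before its own result was seen. Pfn2's entry in the authors' value table, which lies outside the main comparison, was higher on both Hdac6 vector arrays by a log2 difference of 4.26, while neither of its probes was. A rise of Pfn2 transcripts of that size is argued against by the brighter probe, whose upper 95% limit was a log2 fold change of 0.47, and a smaller rise stays open. A candidate explanation is that the table averages, on each array, only those probes of a gene that are well above background: over 16080 values of genes with some but not all probes detected, the mean of the detected probes gave the table's value within 0.01 for 99.81%, and the mean of all probes for 0%. For Pfn2 this averaging gives back 4.26, because the dimmer probe entered the mean on the empty vector arrays and dropped out on the Hdac6 vector arrays. Of the 19 genes that limma called in the table, 18 have several probes, all 18 with fewer detected on both Hdac6 vector arrays, and their table log2 differences ran from 2.75 to 6.44, as for Ndufv2 (5.40), Prdx2 (3.60) and Tyro3 (4.69), picked after their values were seen, while the brightest probe of each moved by at most 0.39 in either direction.

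The remaining gene called in the table was Saa3, which has 1 probe. Fewer probes were detected on both Hdac6 vector arrays than on both empty vector arrays for 307 of 11851 genes with several probes, and the reverse held for 9. Detection was lower over all spots too, at 64.3% and 61.0% on the Hdac6 vector arrays against 66.4% and 65.1%. The 307 and 9 are thus not particular to these genes.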

How the results depend on the processing

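Signal over background limits these results, since 62.2% of the probes were tested and folds against a group with no array well above background are bounds. Other settings gave other counts of changed probes than the main 4, all of them also at least 2-fold: 32 with normexp, 2 with quantile normalization, 0 with median scaling, 2 with no trend in the spread, 2 genes with the mean of a gene's probes and 19 rows with the authors' value table. Leaving out 1 array gave 0 to 310, the lone array being assumed to vary like the other group. The number of lists shifted was 5 to 9 under the settings other than left-out arrays (4 to 5) and an estimated correlation (0). Deviations of same-numbered arrays correlated at -0.35 over all tested probes, as the likeness of empty vector 2 and Hdac6 vector 1 implies. This gave no sign of a pairing but cannot exclude an effect linked to the replicate number. Interferon genes were higher on the arrays numbered 2 in both groups (median 0.45, camera adjusted p = 7.44e-18 at the preset correlation). The replicate block gave 22 changed probes. The crossed replicate block, chosen after seeing the data and following the closest pair of arrays, gave 18. Also chosen after seeing the data, the value table's rows for genes with 1 probe gave 0 (355 at an unadjusted p under 0.05). The log2 fold changes of Saa3 and Saa1 kept their sign in every setting. Spike-in scaling moved the median of all probes to 0.13 and no filter on dim probes to 0.11. Pfn2 reversed to 4.26 in the authors' value table, where averaging over detected probes gives that value back. With an array left out Pfn2 ran from -0.74 to 0.19, and Hdac6 from -0.45 to 0.17, with 0.10 without empty vector 1. The other genes that reversed passed in no setting. With normexp Hdac1 was at -0.0044 and Hdac2 at -0.0127. With median scaling Hdac1 was at -0.0368, Pfn1 at -0.0109 and Hdac2 at -0.0280. With spike-in scaling Hdac7 was at 0.0061 and Hdac5 at 0.0039. In the value table Hdac1 was at -0.0390 and Hdac2 at -0.0193, the latter also among genes with 1 probe (-0.0193). With an array left out the log2 fold change ran from -0.37 to 0.48 for Hdac1, -0.33 to 0.45 for Hdac2, -0.0905 to 0.42 for Hdac3, -0.28 to 0.0658 for Hdac5, -0.38 to 0.16 for Hdac7, -0.0375 to 0.29 for Hdac10, -0.54 to 0.27 for Hdac11 and -0.16 to 0.32 for Pfn1. The medians ran from -0.14 to 0.44 for the NF-kB list and from -0.0936 to 0.37 for the ribosomal list. The cause was not tested for these.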

Other observations

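The fits, settings and gene lists fixed beforehand aside, all tests in this part were chosen after the result was seen. The exception is the histone test, which was chosen before its own result was seen. Genes named in this part, apart from Saa3, Saa1, Hp and Hdac6, were chosen after their values were seen, and the acute-phase genes after Saa3, Saa1 and Hp had been. All 5 probes of the ceruloplasmin gene Cp were higher with the Hdac6 vector, by 1.66-fold to 2.75-fold, and the 2 probes of the complement factor B gene Cfb were at 2.58-fold and 2.92-fold. None of these passed the limma test (adjusted p = 1.00), while both Cfb probes and the Cp probe at 2.75-fold passed with normexp background correction. That Cp probe also passed with the crossed replicate block. Of Farsa, a phenylalanyl-tRNA synthetase gene, 1 probe was at 5.13-fold (adjusted p = 1.00) beside others at 0.924-fold to 1.19-fold. The probe at 5.13-fold passed with normexp and with either replicate block.

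Interferon response genes differed within the groups. Of 55 tested members, 48 were higher on empty vector 2 than on empty vector 1, with a median log2 difference of 0.68, and 44 were higher on Hdac6 vector 2 than on Hdac6 vector 1 (median 0.33, beside 0.20 for all tested genes). The interferon beta gene Ifnb1 read -2.90 and -0.12 on the empty vector arrays and -2.96 and -2.72 on the Hdac6 vector arrays. Ifit1 read 3.61 and 5.40, then 4.49 and 4.69.

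For the rise of Saa3 and Saa1 and the higher values of other NF-kB target genes, leukocytes among the cells were considered. A share large enough to raise the macrophage and leukocyte markers together is argued against by their median log2 fold change of 0.00486 (SD 0.371 over 14 genes, 0 of them at 1 or more, upper quartile 0.112). A smaller share stays open, since it need not move that median. Of the brightest of these markers, Cd68 was at 0.529-fold, Cd14 at 0.987-fold and Ptprc at 0.956-fold. The highest fold was that of C1qb, a dim complement gene, at 1.81-fold (adjusted p = 1.00 for each). A stronger response to transfected DNA cannot be told apart from its absence: the interferon and nucleic acid response genes had a median of -0.0424 over 55 genes, but their median differed by 0.68 between the empty vector arrays alone. An effect of Hdac6 and any other difference between both plasmid preparations stay open and were not tested.

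Empty vector 2 and Hdac6 vector 1 resembled each other more than the arrays of either group did, with an SD of the log2 difference of 0.302 over 32601 probes against 0.465 to 0.553 for the other pairs. Split by vector the arrays gave 4 changed probes (limma), by replicate number 0 (477 at an unadjusted p under 0.05) and with this pair against the rest 428. The pair was picked for its likeness, so the 428 restate that likeness and are no separate evidence. The likeness points to a structure among the samples that the groups do not explain, and 3 splits are too few to give a share under 0.05. More RNA without a poly(A) tail in the pair is a candidate explanation. The 50 tested histone genes picked by their cluster names, most of whose transcripts end without such a tail, were compared between the pair and the rest. Their median log2 difference was 0.225 (36 higher, all probes -0.0898, camera p = 9.62e-07 at the preset correlation). This p cannot decide the explanation, since the split was picked for its likeness. At the preset correlation camera also called 7 of the 32 fixed lists in that split. The shorter histone list fixed beforehand had only 0.0745 (camera adjusted p = 0.350). Rn18s, the ribosomal RNA, read 3.41 and 4.32 on empty vector 1 and Hdac6 vector 2 and 6.89 and 7.31 on the pair. An exchange of an empty vector sample with an Hdac6 vector sample cannot be told apart from the labelled order by the Hdac6 probe (-0.546 between the pair and the rest), which reads the gene's own 3′ end and need not read the insert, nor by Saa3 (-0.08) and Saa1 (0.04), which followed the labels but were picked by a test on the labels.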
